A study of Homo sapiens with 16 samples.

How the data were processed

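ChIP-seq was done on SW480 cells at a stated passage range, with formaldehyde cross-linking, sonication and antibodies against histone marks beside IgG, per the labels' protocols. There were 8 targets and 2 conditions, NC and TGF, with 1 library per target and condition, grouped by the sample titles. The submitters' processing notes name Bowtie2, without a version, and the hg19 build. The peak caller, its threshold, its control and any filter on reads are not given in the sources used here. An IgG library was not analysed here.

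Each deposited list gives a chromosome, a position 1 base wide, a row name and a number. The row names have the form that summit lists of a peak caller carry, and are numbered without gaps from the first to the last row of each list, so no row appears to have been taken out after calling. The deposited score was read from its values as the −log10 of a q-value: its lowest value over all lists was 1.303, just above 1.301, which is the −log10 of 0.05. This reading and the unit are not recorded in the labels. The score is the authors' value for each summit and was used only to rank, filter and describe summits within a list. Peaks were listed per library, with no pooling visible. The row names carry the suffix of a read file for H3K9ac, H3K4m1, H3K36me3 and RNApotII and lack it for the other 4 targets, always alike in both conditions. This split in naming lies between targets, so it does not separate NC from TGF within a target.

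Summits 1 base wide carry no peak width, so covered bases and overlaps of a given fraction could not be computed. In place of the planned overlap of at least 1 base, summits were called shared when they lay within 1 kb of each other, which was planned as an alternative. Shares are given with exact (Clopper-Pearson) 95% intervals, and ratios of numbers of summits with the exact interval of the conditional binomial share. All intervals cover counting error only: they leave out the variation between cultures and immunoprecipitations, which 1 library per group cannot show. No p-values were computed. Depth per library is not recorded in the lists, so the precision of a single summit is unknown. As background, each list was shifted 100 times by a random amount along each chromosome within the span of all summits, with wrapping, which keeps the spacing of its summits. There were 4 lists of fewer than 100 summits, and comparisons of conditions that involve them got no such background.

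Recurrent regions were places where summits of at least 6 of the 8 targets lay within 1 kb of one another; there were 9. Summits were also counted in windows of 100 kb, and the 5 fullest windows and the 5 fullest with none in the other condition were taken from each list of sufficient length. Stretches were built from H3K4m1 NC summits within 1 kb of an H3K9ac NC summit outside recurrent regions, chained over gaps of up to 100 kb; 9 of 15 stretches had at least 3 such summits. Windows, recurrent regions and stretches were defined after the data had been seen. The planned rule for named items, for lists with no annotation of their build, was the 10 strongest summits of each list by score; the strongest of these that the text names follow it, and windows and stretches were chosen by their counts.

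The only annotation at hand was of another build, GRCh38, and coordinates were not converted. The planned counts of promoters, locations relative to genes and 21 gene lists were therefore not run, and no genes are named. The measure of sharing was tested on simulated lists with a known share planted among randomly placed summits. With 20% planted, 20.0% was recovered above background for 21225 H3K27ac TGF summits and 20.6% for 393 H3K9ac NC summits. With 60% planted, 60.1% and 60.7% were recovered. The alternatives tried were merging of summits closer than 1 kb, chromosomes 1 to 22 and X, the better part of each list by score, lists of equal length, other distances, a score of at least 3, and the removal or selection of regions. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.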

Results

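The data were 16 lists of chromatin immunoprecipitation sequencing (ChIP-seq) summits from SW480, an established human colorectal cancer cell line. There were 8 targets, each immunoprecipitated once in a condition labelled NC and once in a condition labelled TGF, so that every list stood for 1 library. The targets were 3 histone H3 acetylations (H3K9ac, H3K18ac and H3K27ac), 4 histone H3 methylations (H3K4m1, H3K4m3, H3K36me3 and H3K27m3) and a target labelled RNApotII, read here as RNA polymerase II. The series title places the work in histone acetylation and the TGF-β pathway in chemoresistance. The labels define neither NC nor the dose or duration behind TGF. The lists held 205363 summits on build hg19. Read depth was unknown, so the number of summits is the only measure of yield per library. No group had a replicate library, so none of the differences between NC and TGF had a replicate check. The 95% intervals are exact and cover counting error only. Shares within 1 kb rise or fall by more than 1.5 times for several targets with a distance of 5 kb or 200 bases, and for some with only the better part of the lists by score. Regions are given by coordinates, because no gene annotation of hg19 was used here.

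The first question was which targets had more or fewer summits in TGF than in NC. The acetylation lists moved in opposite directions. H3K9ac had 393 summits in NC and 9658 in TGF, a ratio of 24.6 (22.2 to 27.3). H3K18ac had 19 and 9445, a ratio of 497 (318 to 826). H3K27ac, which marks active promoters and enhancers, had 35899 in NC and 21225 in TGF, a ratio of 0.591 (0.581 to 0.601), and so fell by 40.9%. H3K27m3, the mark of Polycomb-repressed chromatin, had 50101 and 70404, a ratio of 1.41 (1.39 to 1.42). RNApotII had 1116 and 5357, a ratio of 4.80 (4.50 to 5.12). This rise lay away from H3K27ac: within 1 kb of it RNApotII had 788 and 444 summits, and elsewhere 328 and 4913. In TGF 81.4% of the RNApotII summits had no summit of another target within 1 kb. H3K4m3, a promoter mark, had 707 and 870, a ratio of 1.23 (1.11 to 1.36). Among H3K4m3 summits with a score of at least 3 the ratio was 1.10, with an interval that included 1 (0.962 to 1.25). Chromosomes 15 and 21, with the most H3K4m3 summits in NC, held 323 in NC and 125 in TGF. Without them the counts were 384 and 745, a ratio of 1.94 (1.71 to 2.20), but they were picked after the data had been seen by their NC counts, which favours a higher ratio. H3K4m1, a mark of enhancers, had 107 and 24, a ratio of 0.224 (0.138 to 0.352). H3K36me3, a mark of transcribed gene bodies, had 16 and 22, and its ratio of 1.38 had an interval that included 1 (0.690 to 2.80). The lists of H3K18ac NC, H3K4m1 and H3K36me3 held at most 107 summits each. Whether these immunoprecipitations or their peak calling failed is unknown, so the ratios of these 3 targets describe the lists alone. For the other targets too, a difference of condition cannot be told from a difference in the yield of a library.

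**Figure D1:**
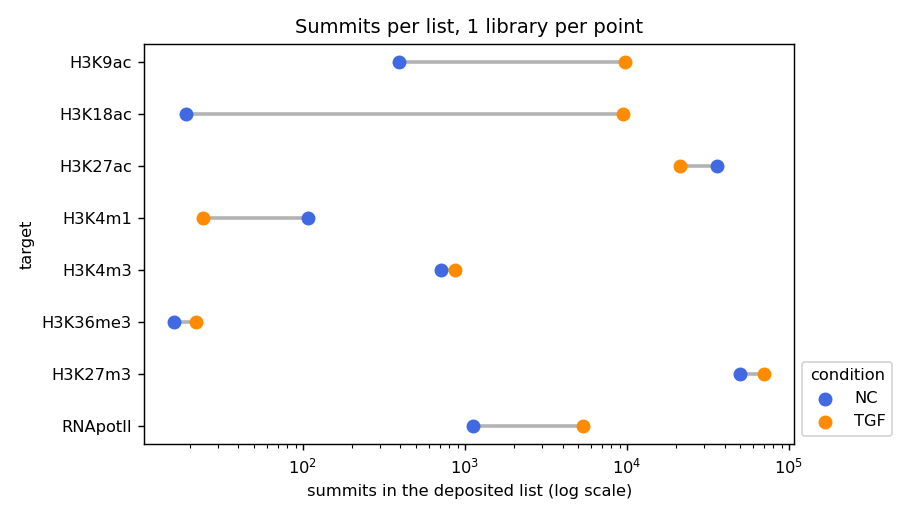
Number of summits in each of the 16 lists on a log axis, 1 point per library, with blue points for NC and orange points for TGF of the same target. H3K9ac and H3K18ac had 24.6 and 497 times as many summits in TGF as in NC, while H3K27ac had 0.591 times as many.

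The direction of RNApotII depended on which summits were counted. Within 1 kb of an H3K27ac summit of either condition, RNApotII had 788 summits in NC and 444 in TGF, a ratio of 0.563 (0.500 to 0.634), and elsewhere 328 and 4913, a ratio of 15.0 (13.4 to 16.8). H3K4m1 had 10 and 13 summits near H3K27ac, a ratio of 1.3 with an interval that included 1 (0.527 to 3.31). Its summits elsewhere numbered 97 and 11, a ratio of 0.113 (0.0548 to 0.212). H3K4m3 split the other way from RNApotII, with 168 and 586 summits near H3K27ac, a ratio of 3.49 (2.93 to 4.17). Elsewhere it had 539 and 284, a ratio of 0.527 (0.455 to 0.609). The share of H3K4m3 summits near H3K27ac was 23.8% (20.7 to 27.1) in NC and 67.4% (64.1 to 70.5) in TGF. Part of this split came from chromosomes 15 and 21: without them H3K4m3 had 231 and 187 summits elsewhere, a ratio of 0.810 (0.664 to 0.986), and the share near H3K27ac was 39.8% (34.9 to 44.9) in NC and 74.9% (71.6 to 78.0) in TGF. For RNApotII the share near H3K27ac was 70.6% (67.8 to 73.3) in NC and 8.29% (7.56 to 9.06) in TGF. These splits were chosen after the data had been seen.

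**Figure D2:**
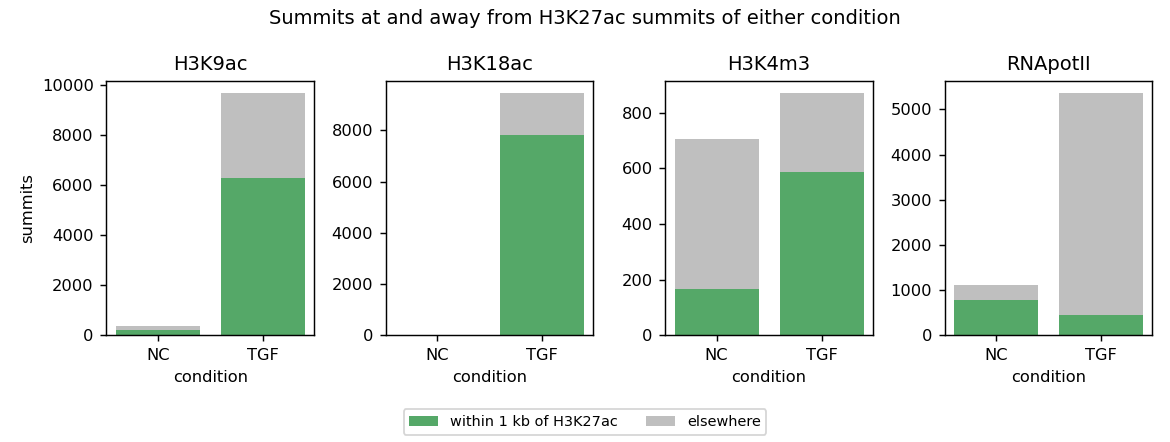
Number of summits of 4 targets in NC and TGF, stacked by whether an H3K27ac summit of either condition lay within 1 kb (green) or not (grey), each panel with its own linear axis from 0. Near H3K27ac, H3K4m3 summits numbered 168 in NC and 586 in TGF, and RNApotII summits 788 and 444; the H3K18ac NC bar of 19 summits is too low to be seen.

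The next question was whether the lists of a target marked the same places in NC and TGF. For H3K27ac, 61.4% (60.7 to 62.1) of the 21225 TGF summits lay within 1 kb of an NC summit, against 2.54% on average (2.12 to 3.38) over 100 random placements of the list. In the other direction 38.1% (37.6 to 38.6) of the NC summits were found in TGF, and 22214 were not. The share found in TGF was 26.7% (25.2 to 28.1) in the lowest of 10 equal parts of the NC list by the authors' score and 66.8% (65.3 to 68.4) in the highest. With both lists reduced to equal length by score, 46.4% of the TGF summits were shared.

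The H3K27ac lists differed over whole neighbourhoods. In 100 kb windows, H3K27ac had more summits in NC in 5737 and more in TGF in 1908. Of the 993 windows with 10 or more NC summits, 54 held none in TGF. The fullest of them were on chromosome 3 at 187300001 to 187400000 (27 NC summits), chromosome 6 at 2500001 to 2600000 (24) and chromosome 10 at 29500001 to 29600000 (22). Of the 467 windows with 10 or more TGF summits, 5 held none in NC, among them chromosome 2 at 10600001 to 10700000 (14 TGF summits) and chromosome 9 at 137400001 to 137500000 (13). Both also held 7 H3K18ac TGF summits each, and the window on chromosome 2 had 3 H3K27m3 summits in NC and 0 in TGF. On chromosome 20 at 49900001 to 50000000 the H3K27ac count was 4 in NC and 37 in TGF, beside 26 H3K18ac TGF summits.

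The strongest H3K27ac summit in TGF lay on chromosome 8 at 128232391, with a score of 24.2. The strongest H3K18ac summit in TGF lay beside it at 128233155, with a score of 42.1, and an H3K27ac summit among the 10 strongest in NC at 128233628, with a score of 20.4. The strongest H3K27ac summits in NC were on chromosome 10 at 74083177 and chromosome 5 at 133080049, both with a score of 23.5. The window on chromosome 10 at 74000001 to 74100000 was also the fullest of H3K27ac and of H3K18ac in TGF, with 54 and 45 summits, and held 18 of H3K9ac.

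Most of the few H3K9ac NC summits were also found in the TGF list, which held many more. Of the 393 NC summits, 83.5% (79.4 to 87.0) lay within 1 kb of a TGF summit, against 0.858% on average (0 to 2.54) over random placements. With both lists reduced to equal length by score the share was 36.4%. Of the 9658 TGF summits, 3.72% (3.35 to 4.11) lay near an NC summit, and 9299 did not. Of these 9299, 52.7% (51.7 to 53.8) were within 1 kb of an H3K27ac NC summit. Windows with no H3K9ac summit in NC and the most in TGF were on chromosome 9 at 132300001 to 132400000 (22 summits), chromosome 7 at 1500001 to 1600000 (19) and chromosome 1 at 154900001 to 155000000 (16). They held 32, 21 and 21 H3K27ac summits in NC. The 10 strongest H3K9ac NC summits were all more than 1 kb from any H3K27ac summit, and 25.2% (21.0 to 29.8) of the list lay in 9 short stretches described with H3K4m1. Outside these stretches and the recurrent regions, 78.1% (72.8 to 82.8) of 283 NC summits were found in TGF.

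H3K18ac had next to no summits in NC. Of its 19 NC summits 9 lay in recurrent regions, places where at least 6 of the 8 targets had summits, and without these the TGF to NC ratio was 943.5. Of the 9445 TGF summits, 9436 were not near an NC summit, and 65.0% (64.0 to 66.0) of these were within 1 kb of an H3K27ac NC summit. The fullest windows were on chromosome 10 at 74000001 to 74100000 (45 summits) and chromosome 12 at 52600001 to 52700000 (43). On chromosome 20 at 52700001 to 52800000 there were 29. All 3 had no H3K18ac summit in NC and 45, 37 and 26 H3K27ac summits there.

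H3K27m3 had more summits in TGF. Of the 6865 windows of 100 kb that held it in TGF, 5628 held it in NC too. Of the 50101 NC summits, 60.3% (59.9 to 60.7) lay within 1 kb of a TGF summit, against 5.12% on average (4.18 to 7.45) over random placements. Of the 70404 TGF summits 44.8% (44.4 to 45.2) lay near an NC summit. Windows with 10 or more summits numbered 1718 in NC and 2426 in TGF, and 1563 of them had 10 or more in both. The fullest NC windows, chromosome 1 at 204900001 to 205000000 and chromosome 17 at 75900001 to 76000000, had 62 and 57 summits in NC and 58 and 65 in TGF. Other windows among the fullest in TGF had fewer in NC, with 37 in NC and 64 in TGF on chromosome 11 at 33500001 to 33600000 and 30 and 63 on chromosome 13 at 112800001 to 112900000. Some were full in TGF alone, among them chromosome 5 at 136200001 to 136300000 (29 in TGF, 0 in NC) and chromosome 8 at 123400001 to 123500000 (23 and 0). The fullest window of NC alone, on chromosome 11 at 78600001 to 78700000, had 13 and 0. The strongest summits were on chromosome 20 at 47131970 in NC, with a score of 11.2, and on chromosome 17 at 36298187 in TGF, with a score of 14.0.

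**Figure D3:**
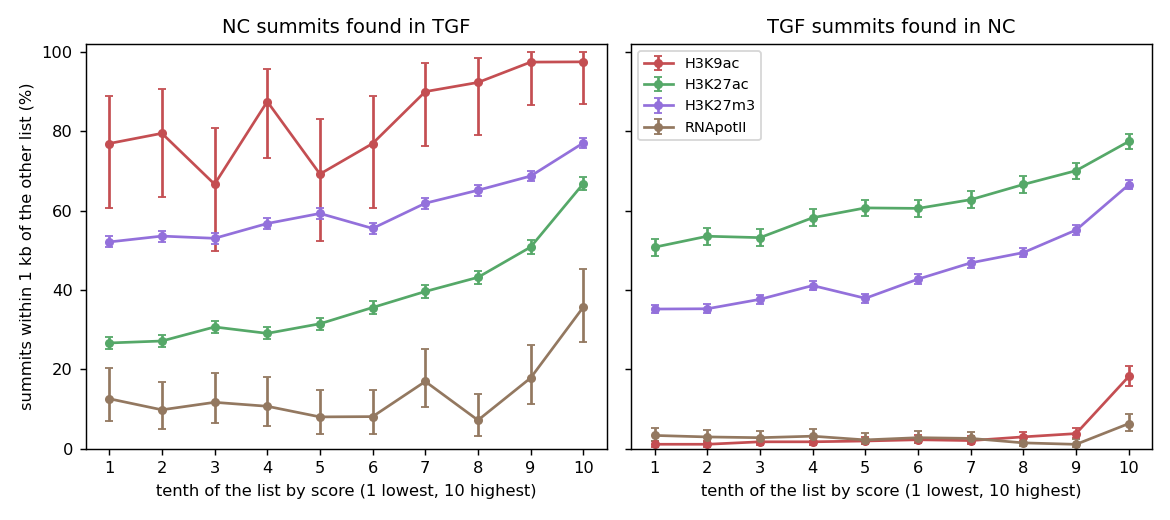
Percent of summits with a summit of the same target within 1 kb in the other condition, in 10 equal parts of the list by the authors' score from 1 (lowest) to 10 (highest), with exact 95% intervals as error bars; the left panel shows NC summits and the right panel TGF summits of 4 targets. For H3K27ac NC the share was 26.7% in the lowest and 66.8% in the highest part; for H3K27m3 NC it was 52.1% and 77.1%.

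For the promoter mark H3K4m3, 27.2% (23.9 to 30.6) of the 707 NC summits lay within 1 kb of a TGF summit, against 0.140% on average over random placements. Of the 870 TGF summits 19.7% (17.1 to 22.5) lay near an NC summit, against 0.105%. In the highest of 10 equal parts by score the shares were 71.8% (59.9 to 81.9) in NC and 65.5% (54.6 to 75.4) in TGF. Of the 10 strongest summits, however, 5 in NC and 6 in TGF lay in recurrent regions. Only 0 in NC and 2 in TGF of these 10 were within 1 kb of H3K27ac of either condition. Many NC summits were crowded into a few windows, on chromosome 21 at 11000001 to 11100000 (29 in NC, 8 in TGF), 11100001 to 11200000 (27 and 13) and 9800001 to 9900000 (26 and 7), and on chromosome 15 at 20500001 to 20600000 (25 and 5). In TGF 68.7% (65.5 to 71.8) of the H3K4m3 summits were within 1 kb of H3K9ac and 49.7% (46.3 to 53.0) within 1 kb of H3K27ac. In NC 20.4% (17.5 to 23.5) were within 1 kb of H3K27ac. In the better part of both lists by score the shares near H3K27ac were 32.0% in TGF and 10.5% in NC. In TGF, 5 H3K4m3 summits lay in a window on chromosome 1 at 155100001 to 155200000 that had none in NC.

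H3K4m1 in NC lay mostly near H3K9ac and seldom near H3K27ac. Of its 107 summits 98 were within 1 kb of an H3K9ac NC summit, 68 near RNApotII in TGF and 6 near H3K27ac in NC. Most lay in 9 stretches of 2.61 to 112 kb, which held 83 H3K4m1 NC summits, 99 H3K9ac NC, 104 H3K9ac TGF and 71 RNApotII TGF. The same stretches held 0 H3K4m1 TGF, 7 RNApotII NC, 3 H3K27ac NC, 4 H3K27ac TGF, 4 H3K27m3 NC and 7 H3K27m3 TGF summits, and 0 of H3K18ac, H3K4m3 or H3K36me3 in either condition. The 5 with the most matched H3K4m1 summits were on chromosome 7 at 55177569 to 55273099, 116339749 to 116435764 and 140422335 to 140534576, chromosome 17 at 37856452 to 37883634 and chromosome 3 at 178916785 to 178952036. Without summits near only those targets whose row names had the same form, H3K4m1 had 21 summits in NC and 24 in TGF, a ratio of 1.14 (0.610 to 2.16). H3K36me3 summits were few, and 12 of 16 in NC and 11 of 22 in TGF lay in recurrent regions.

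**Figure D4:**
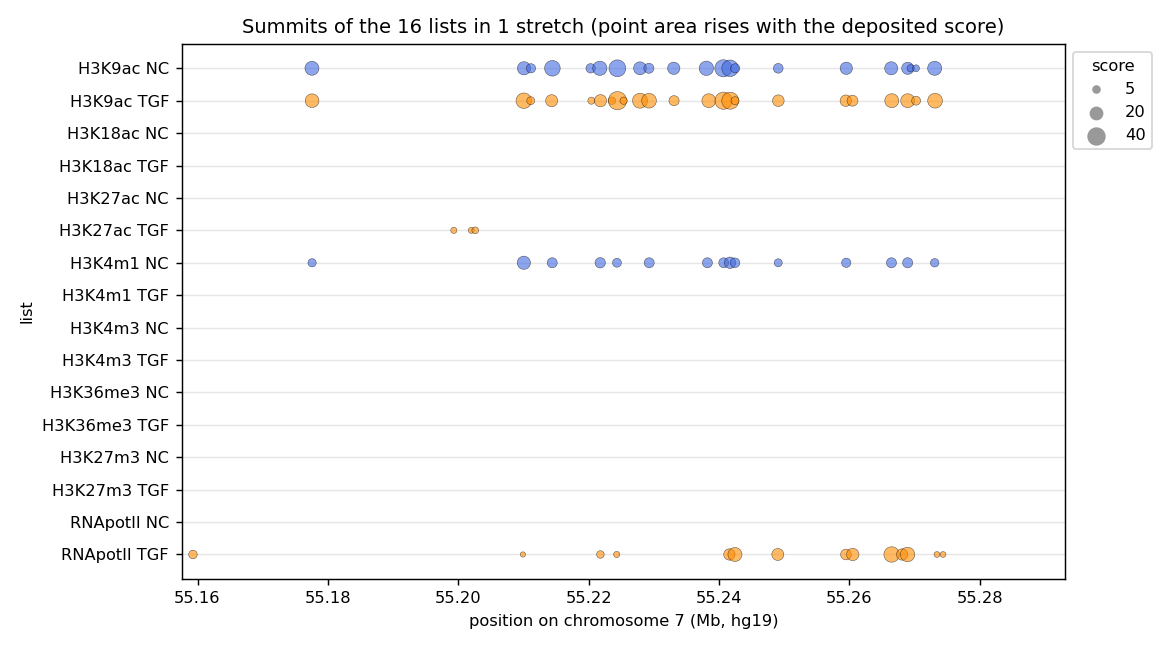
Position of the summits of all 16 lists on chromosome 7 from 55157569 to 55293099 (hg19, shown in Mb), 1 row per list, with point area rising with the authors' score, blue for NC and orange for TGF. H3K9ac in both conditions, H3K4m1 in NC and RNApotII in TGF had summits within 1 kb of one another at many positions, though not at all of them, while H3K27ac had 3 TGF summits between them, with scores of at most 5.09.

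RNApotII shared few sites between NC and TGF. Of the 1116 NC summits 13.9% (11.9 to 16.1) were found in TGF, against 0.371% on average over random placements, and of the 5357 TGF summits 2.89% (2.46 to 3.38) were found in NC. With both lists at equal length by score the NC share was 3.67%. Of the NC summits, 59.1% (56.1 to 62.0) were within 1 kb of H3K27ac in NC and 69.3% (66.5 to 72.0) within 1 kb of H3K9ac in TGF. In the better part of both lists by score 35.7% were near H3K27ac in NC. Of all NC summits only 4 were near H3K27m3 in NC, 0.358% (0.0977 to 0.915) against 3.53% over random placements. In TGF 81.4% (80.4 to 82.5) of the summits had no summit of another target within 1 kb, and 4.33% (3.80 to 4.91) were near H3K27m3, against 4.35% over random placements. The fullest TGF windows were on chromosome 2 at 179400001 to 179500000 (57 summits) and 179500001 to 179600000 (38). They held 1 and 0 RNApotII summits in NC and none of any histone mark.

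The last question was how the marks lay relative to one another. H3K27ac and H3K27m3, which occupy the same lysine, hardly met: 1 of the 35899 H3K27ac NC summits was within 1 kb of H3K27m3 in NC, against 3.51% over random placements. In TGF 4 of 21225 were, against 4.90%. Of the H3K18ac and H3K9ac summits in TGF, 2 of 9445 and 8 of 9658 were near H3K27m3, against 4.91% and 4.83% over random placements. Within 1 kb, few places changed from one of these marks to the other. Of the 19882 H3K27m3 summits found in NC alone 6 were near H3K27ac in TGF, and of the 8194 H3K27ac summits found in TGF alone 7 were near H3K27m3 in NC. In TGF 67.0% (66.1 to 68.0) of H3K18ac and 45.7% (44.7 to 46.7) of H3K9ac summits were within 1 kb of H3K27ac, against 1.60% and 1.63% over random placements. H3K18ac and H3K9ac coincided less: 17.0% (16.3 to 17.8) of H3K18ac TGF summits were near H3K9ac TGF, against 0.770% over random placements. The H3K9ac TGF list is shorter than that of H3K27ac TGF, which lowers such a share by construction. Of the H3K18ac TGF summits 14.5% (13.8 to 15.2) were near both H3K9ac and H3K27ac.

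**Figure D5:**
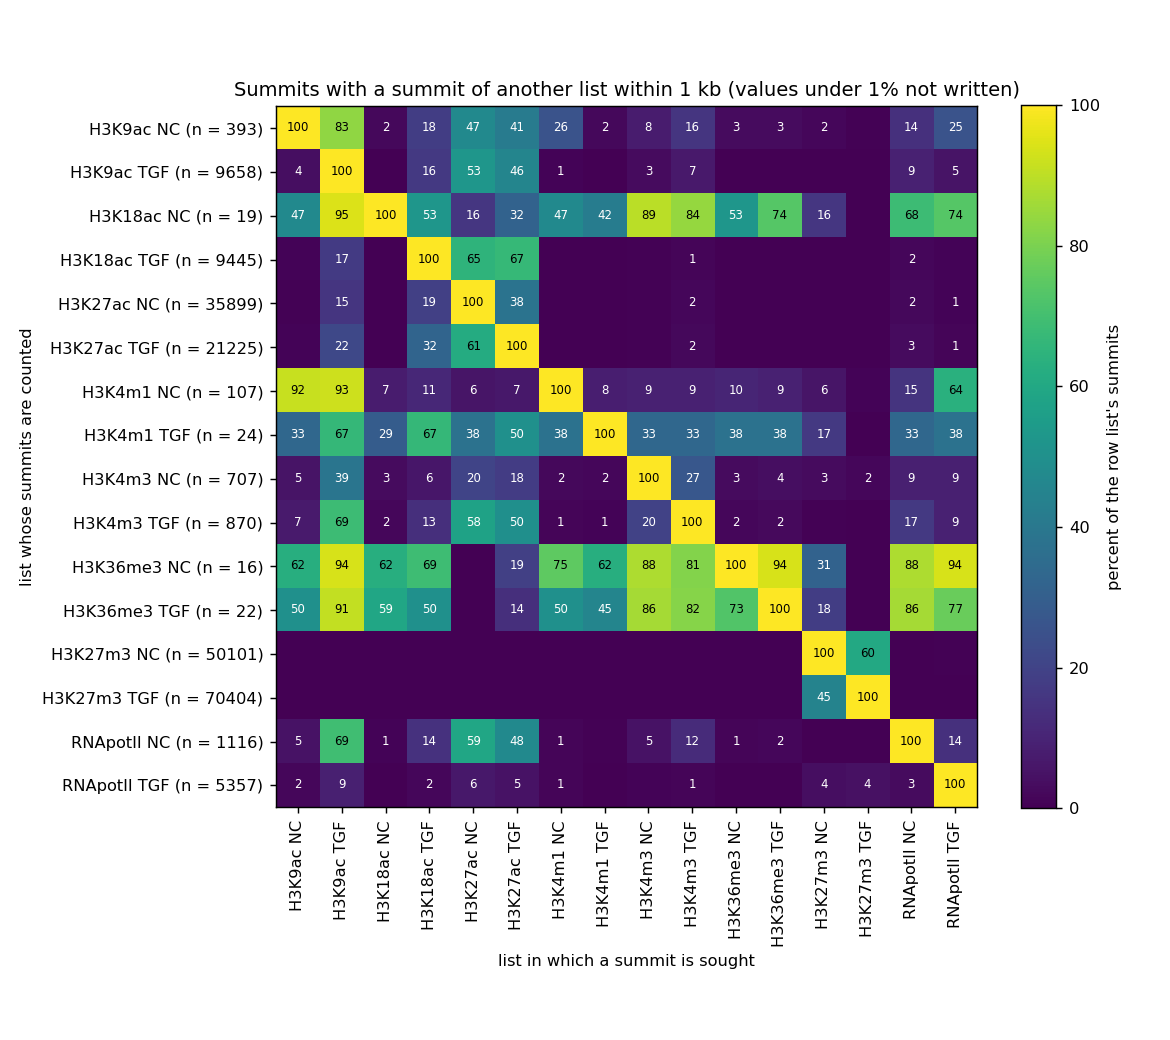
Percent of the summits of each list (rows, with the number of summits) that had a summit of another list (columns) within 1 kb, on a colour scale from 0 to 100%. H3K27m3 shared 60.3% and 44.8% between its own lists and next to nothing with other targets, and the RNApotII TGF row is nearly empty, unlike the RNApotII NC row with 69.3% in H3K9ac TGF.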

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

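All tests in this part were chosen after the results they bear on had been seen, at least in part. Summits on the mitochondrial genome, which belong to no comparison of histone marks, numbered 4 in RNApotII TGF and 0 in RNApotII NC. This was singled out because it lies outside the main measurement and was above the NC library. They lay at 719, 2635, 7788 and 14645, with scores up to 133. H3K9ac had 1 such summit in each condition, and the remaining lists had none.

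The lists of H3K9ac, H3K4m1 NC and RNApotII TGF shared strong summits in 9 stretches, 489 kb in all, which held 3 H3K27ac summits in NC and 4 in TGF. A candidate explanation is reads from another kind of library, such as one enriched for chosen genes. RNApotII TGF, which was not used to choose the stretches, had 71 summits there, against at most 14 over random placements. The lists with these strong summits all have the same form of row names. Of the other lists of that form, RNApotII NC had 7 summits there, and H3K4m1 TGF, H3K36me3 NC and H3K36me3 TGF had 0. The last 3 held only 24, 16 and 22 summits in all, too few to tell. Of the lists without that form, H3K18ac and H3K4m3 had 0 there in either condition. H3K27ac had 3 in NC and 4 in TGF, and H3K27m3 4 and 7. Amplified DNA and active chromatin stay open: 4 short NC lists not used to choose the stretches had 7 summits there, against at most 2 over random placements, but 6 of them in 1 stretch, and the share of H3K9ac NC summits near H3K27ac, 1.01% in the stretches against 73.9% elsewhere, only restates how the stretches came to notice. For the RNApotII TGF list as a whole, the stretches included, the source of the reads stays open too. Its 536 strongest summits were near H3K27ac in 6.34% and the remaining 4821 in 8.50%. RNApotII NC had no gradient either (71.4% and 70.5%), so the test has no contrast. Polymerase at places without H3K27ac stays open as well. Of the 4913 RNApotII TGF summits away from H3K27ac, 4.52% (3.95 to 5.14) were near H3K9ac or H3K4m3, above the highest random placement of 1.12%. Without the stretches and recurrent regions 3.08% still were. Reads of any source that gather near genes would also exceed random placement, so this test cannot tell polymerase from other sources.

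The H3K27ac list was shorter in TGF, and 54 of the 993 windows with 10 or more NC summits held none in TGF. Keeping the 21225 best NC summits by score, as under a stricter cutoff on the NC scores, emptied 0 of these windows, against 54 in TGF. The highest of 100 random thinnings of the NC list emptied 1. Windows picked for 10 or more NC summits can hardly be emptied in either way, so both outcomes were nearly fixed in advance. A stricter cutoff therefore stays open. Both tests resample the NC library, so a lower depth or yield of the TGF library stays open. A regional loss of H3K27ac under the TGF condition stays open as a hypothesis, untested, because condition and library coincide with 1 library each.

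The H3K9ac list was longer in TGF. Low yield of the NC immunoprecipitation may account for it: outside the stretches and recurrent regions 78.1% (72.8 to 82.8) of 283 NC summits were found in TGF, and the TGF summits near them had a median rank at the 75.2 percentile of TGF scores, as a weak library that keeps its strongest sites would show. A rise in H3K9ac under the TGF condition would leave the same picture, so it stays open as well. For H3K18ac only 10 NC summits lay outside recurrent regions, 1 of them near TGF, too few for the same test, and a failed NC immunoprecipitation or peak calling stays open.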

How the results depend on the processing

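The alternatives of merging, chromosomes, better part by score and equal length were chosen before the data were examined, except merging for the ratio of chromosome 20 to chromosome 18; that, the other distances, the score minimum and the removal or selection of regions were chosen after the data had been seen. The direction of the TGF to NC ratio was kept for H3K9ac, H3K18ac, H3K27ac and H3K4m3 under every alternative run, but for H3K4m3 the interval included 1 with a score of at least 3 (0.962 to 1.25), and its summits away from H3K27ac had a ratio of 0.527. Of 162 values under alternatives 60 stayed within the 95% interval of the reported value. H3K36me3 had no direction beyond counting error. Restricting the count to chromosomes 1 to 22 and X moved no ratio out of its interval, and taking the better part of each list fixes the ratio by construction. No paired analysis was possible because each group had 1 library. Counts of promoters, locations relative to genes and gene lists, covered bases and overlap of 50% of a peak were not run, for want of an annotation of the build and of peak widths. With 1 library per group and no read depth, the difference between a condition and the yield of a library cannot be measured for any target.

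Counted within 1 kb of H3K27ac, the ratio reversed for RNApotII (0.563), H3K4m1 (1.3) and H3K27m3 (0.875, from 8 and 7 summits), and was 29.4 for H3K9ac, 1304 for H3K18ac (from 6 NC summits) and 3.49 for H3K4m3. Without summits near only those targets with the same form of row names, it reversed for H3K4m1 (1.14) and was 32.0 for H3K9ac and 5.32 for RNApotII. Without recurrent regions it was 943.5 for H3K18ac. Without chromosomes 15 and 21 it was 1.94 for H3K4m3. With merging it was 0.602 for H3K27ac and 1.37 for H3K27m3. With a score of at least 3 it was 0.536 for H3K27ac, 1.10 for H3K4m3 and 1.87 for H3K27m3. The intervals of the reversed ratios of H3K4m1 and H3K27m3 included 1. Inside the interval of the reported ratio, but over 1.5 times from it, were H3K36me3 without recurrent regions (2.75, from 4 and 11 summits), and H3K18ac (323) and H3K4m1 (0.143) with a score of at least 3. The cause was not tested for these ratios.

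The share found in the other condition is given for H3K9ac NC, H3K27ac TGF, H3K4m3 NC, H3K27m3 NC and RNApotII NC in this order. It was 1.53%, 0.137%, 0.283%, 0.154% and 0.0896% at the same base, 57.8%, 26.3%, 16.7%, 21.8% and 8.69% within 200 bases, 89.8%, 81.2%, 44.7%, 87.5% and 17.7% within 5 kb, and 36.4%, 46.4%, 23.9%, 49.4% and 3.67% with lists of equal length. In the better part of both lists it moved to 49.4% for H3K27ac, 45.3% for H3K27m3 and 9.68% for RNApotII, and with merging to 57.2% for H3K27ac, 23.4% for H3K4m3 and 55.1% for H3K27m3.

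The share near H3K27ac of the same condition is given for H3K18ac TGF, H3K9ac TGF, H3K4m3 NC, H3K4m3 TGF, RNApotII NC and RNApotII TGF in this order. It was 0.180%, 0.186%, 0%, 0.115%, 0% and 0% at the same base, 28.2%, 19.8%, 10.3%, 24.8%, 22.3% and 1.68% within 200 bases, 87.6%, 61.7%, 25.6%, 59.5%, 73.7% and 9.54% within 5 kb, and 55.6%, 31.4%, 10.5%, 32.0%, 35.7% and 2.54% in the better part of both lists. The share of H3K27ac near H3K27m3 was 0% in NC and 0.00471% in TGF within 200 bases, 0.184% and 0.349% within 5 kb, and 0% in both at the same base and in the better part of the lists. A wider distance or a longer list raises such shares by construction. A further 28 values, mostly shares of the longer list in the shorter, also left their intervals.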

Other observations

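Summits per chromosome and the sharing of RNApotII NC with other NC lists were planned; the chromosomes named here and the other observations were chosen after the data had been seen.

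The density of listed summits of both H3K27 marks varied between chromosomes. These counts per Mb were not corrected for copy number, mapping or effects of the peak caller, so they do not measure the marks alone. Chromosome 20 had 43.9 H3K27m3 summits per Mb in NC and 54.3 in TGF, and 18.9 and 14.5 of H3K27ac. Chromosome 11 had 30.9 and 44.0 of H3K27m3, and 15.3 and 10.2 of H3K27ac. H3K27ac was densest on chromosome 17, with 27.01 in NC and 17.1 in TGF, where H3K27m3 had 31.2 and 41.0. Chromosome 9 had 14.2 and 8.42 of H3K27ac beside 13.3 and 16.6 of H3K27m3. The lowest densities were on chromosome 4, with 1.69 and 1.65 of H3K27m3 and 1.98 and 0.681 of H3K27ac, followed by chromosomes 18 and X. Chromosome 4 was the exception to the higher H3K27m3 count in TGF, with 323 summits in NC and 316 in TGF. With summits closer than 1 kb merged it had 304 in both. The ratio of chromosome 20 to chromosome 18 was 10.4 in H3K27m3 NC, 10.6 in H3K27m3 TGF, 4.26 in H3K27ac NC and 6.87 in H3K27ac TGF.

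The places where H3K27ac was found in TGF alone carried other acetylations more often than those found in NC alone carried them in TGF. Of the 8194 H3K27ac summits in TGF alone, 22.2% (21.3 to 23.2) were near H3K18ac TGF and 14.7% (14.0 to 15.5) near H3K9ac TGF. Of the 22214 in NC alone, 7.83% (7.48 to 8.19) and 9.04% (8.67 to 9.43) were. Over all 21225 H3K27ac TGF summits the shares were higher, 32.1% (31.5 to 32.7) and 21.7% (21.1 to 22.2). The places in TGF alone thus carried the other acetylations less often than the TGF list as a whole. The windows on chromosome 3 at 187300001 to 187400000, chromosome 6 at 2500001 to 2600000 and chromosome 10 at 29500001 to 29600000, which had 27, 24 and 22 H3K27ac summits in NC and none in TGF, held 1, 0 and 0 H3K18ac TGF summits and no H3K9ac or H3K27m3 summit in either condition.

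Of the 1116 RNApotII NC summits, 773 were within 1 kb of H3K9ac in TGF and 53 near H3K9ac in NC. For H3K27ac, 531 were near a TGF summit, 659 near an NC summit and 788 near a summit of either condition.

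The distance between shared summits differed between pairs of lists. H3K4m1 NC and H3K9ac NC summits within 1 kb of each other were 36.5 bases apart in the median, and RNApotII TGF and H3K9ac NC 68 bases, against 215.5 for H3K27ac NC and H3K9ac NC and 325 for H3K27ac NC and RNApotII NC.

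The highest scores of several lists came from recurrent regions. On chromosome 7 at 61968980 to 61969147, 14 of the 16 lists had a summit, with the highest score, 111, in RNApotII NC. Of the 10 strongest RNApotII NC summits 9 lay in recurrent regions. Of the 9 recurrent regions 7 lay within 77.6 kb of the longest stretch of their chromosome without any summit, and both others on chromosome 21 at 9698998 to 9699628 and 9827259 to 9827387.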
